A study of Homo sapiens with 9 samples.

How the data were processed

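RNA-seq was made from DOHH2 cells in culture on the day of grafting and from human CD20-positive cells recovered from femurs of grafted RAGγc mice at day 19 and day 40, with 3 libraries per group. Per the labels' protocols, femurs were flushed and digested with enzymes, mouse blood cells were depleted with beads against CD45 and Ter119, and human cells were sorted on CD20. The deposited values are whole-number counts of reads per gene, not normalized, for 58243 Ensembl gene identifiers per library. Reads were checked with FastQC 0.11.5, aligned to hg38 with STAR 2.5.2a and counted with featureCounts 1.4.6, and DESeq2 1.40.1 was used, per the submitters' processing notes. The gene annotation, the strand setting, the handling of reads that map to several places, read trimming and the handling of mouse reads are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and most such genes are named as overlapping in the report. AHSA1, ERAP2, PLIN4, RUNX2 and SQSTM1 also overlap other genes on the opposite strand. Reads of near-identical paralogs, such as the HLA genes, the histone genes and HSPA1A and HSPA1B, are uncertain because the handling of reads that map to several places is not stated.

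Gene symbols and positions on hg38 were taken from GENCODE release 29, which named 57980 of the 58243 identifiers and left 263 without a symbol. Groups came from the sampling day in the labels. Libraries held between 21071239 and 29456271 counts. A count of 0 was treated as allowing up to 3 counts. This floor and the 95% intervals of ratios cover counting error only, because reads without molecular identifiers are not independent molecules.

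Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr, which left 15163 genes. Library sizes were scaled by TMM, and the quasi-likelihood F-test was run in a model with a coefficient per group over all 9 libraries, so that the groups shared an estimate of the spread. The contrasts were day 19 against day 0, day 40 against day 0, day 40 against day 19, and the mean of both femur groups against day 0. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Every adjusted p of a gene in the text comes from this two-sided test unless another tool is named. CPM values use the TMM-scaled library sizes and are given as mean ± SD of 3 libraries.

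The lists of 26 gene groups and 7 sets of cell type markers were fixed before the data were examined, as were the test design, the rule for naming genes and most processing alternatives. Lists with at least 5 tested members (all 26 gene groups and no marker set) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01, and again with the correlation estimated per list. The lists were also tested with fry in limma, a rotation test that allows for correlated members. It asks whether a list changed at all, not whether it changed more than other genes. Adjustment was over the 26 lists of a comparison. Members were also counted by their own test, with p-values adjusted over all genes or over the list alone. Genes were named by rule. The rule took up to 8 of the largest rises and 8 of the largest falls per comparison among called genes with at least 5 CPM in the higher group and no overlap between libraries, up to 3 called members with the smallest p per list (or, where no member was called, the 1 with the smallest p), and a fixed set (MS4A1, PTPRC, BCL2, BCL6, MYC, CXCR4, TNF, LTA, LTB, TGFB1, MKI67, B2M and MALAT1). Genes outside the rule are said to be chosen after the values were seen. Between day 40 and day 19, only named genes that were called in every alternative, or that were among the largest rises and falls, are given.

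The procedure was tested on simulated counts drawn from the means and library sizes of the 15163 genes, with 200 genes changed. It recovered 97.0%, 92.4% and 87.9% of changes of log2 size 2 for day 19 against day 0, day 40 against day 0 and day 40 against day 19, and 71.6%, 76.1% and 64.2% of changes of log2 size 1. For log2 size 0.5 it recovered 34.3%, 49.3% and 46.3%. Unchanged genes made up 6.41%, 4.35% and 8.44% of the calls. Of the lists, camera called the 1 moved list in each comparison, and also 1 unmoved list for day 40 against day 19. Genes were simulated independently, so this check gives no rate of false calls for lists with correlated members. Far fewer genes were changed than the 8007 called at day 19, so scaling and error rates under so wide a change were not tested.

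Replicate numbers were given in accession order and name a sampling period by the dates in the titles. By these dates the day 19 cells were sorted 18, 19 and 19 days after the culture library of the same period. The day 40 cells were sorted 11, 26 and 39 days after it. Those sorted at 11 and 26 days cannot be day 40 grafts from that culture date, so a period is not always a single graft. Deviations from the group means correlated between libraries of a period at 0.03, -0.05 and 0.12 for culture and day 19, at 0.08, 0.20 and 0.17 for culture and day 40, and at 0.10, 0.13 and 0.31 for day 19 and day 40. By the criterion that every pair exceeds 0.1, the period paired the femur groups with each other but not with culture. The fit with the period as a block was an alternative.

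Alternatives were DESeq2 size factors (RLE) or total library size for scaling, no count filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 and limma voom with quality weights as tests, a fit of the compared libraries alone, the period as a block, removal of 451 immunoglobulin and mitochondrial genes before scaling, and leaving out each of the 9 libraries. A correction for GC content and exon length, available for 99.7% of tested genes, was added after the data were examined. Mouse transcripts were not analysed here, since the counts cover human identifiers.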

Results

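The data were bulk RNA-seq counts from DOHH2, an established human B-cell lymphoma line that derives from a transformed follicular lymphoma. The 9 libraries formed 3 groups of 3. The culture group held cells in culture on the day of grafting (day 0). The femur groups held human CD20-positive cells that were recovered from the femurs of grafted RAGγc mice, an immunodeficient mouse strain that accepts human cells, at day 19 or at day 40. Libraries held between 21071239 and 29456271 counts. The labels do not name the cultures or animals behind the libraries. By the dates in the titles the libraries of a group were taken months apart, as separate samplings. P-values measured the spread between these samples, which may be technical in part. Cultured cells did not pass through the bone digestion, bead depletion and sorting that the femur cells went through, so this handling differed between culture and femur in every comparison with day 0.

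Libraries of a group resembled each other, with correlations across genes of log2 CPM (counts scaled to library size) between 0.987 and 0.993. Culture and day 19 libraries correlated at 0.942 to 0.955, culture and day 40 libraries at 0.953 to 0.962, and the femur groups with each other at 0.983 to 0.989. The first principal component held 69.5% of the variance and separated culture from femur. Mitochondrially encoded genes took 5.57% ± 0.653 of the counts in culture, 8.07% ± 0.566 at day 19 and 8.28% ± 0.389 at day 40 (SD, n = 3). Cytosolic ribosomal protein genes took 11.2% ± 1.61, 8.57% ± 0.208 and 8.90% ± 0.392, and culture replicate 2 was the highest at 13.1%.

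The comparison of day 19 with day 0 asked how the lymphoma cells differed after growth in bone marrow. In the femur 13 of 22 germinal-centre B-cell genes fell and 5 rose, while 14 of 15 MHC class I, 20 of 29 interferon response and 15 of 20 immediate early genes rose. None of these lists was called by camera with an estimated correlation (adjusted p = 0.571 to 0.627). By fry the adjusted p was 1.41e-04 for germinal-centre, 1.62e-04 for class I, 0.0031 for interferon and 0.0027 for immediate early genes. Since fry does not compare a list with other genes, and 52.8% of all genes were called at day 19, it does not set these lists apart. BCL6, the master repressor of the germinal-centre programme, fell from 428 ± 38.1 to 56 ± 2.88 CPM (SD, n = 3; log2 fold change -2.93, SE 0.08, adjusted p = 1.68e-10; chromosome 3, 187721377 to 187745727). LMO2 fell from 63.7 ± 20.1 to 0.970 ± 0.379 CPM. CXCR4, the receptor for the marrow chemokine CXCL12, rose from 123 ± 7.15 to 572 ± 68.3 CPM (log2 fold change 2.22, SE 0.10, adjusted p = 1.03e-08; chromosome 2, 136114349 to 136118165). MS4A1, which encodes the CD20 protein used for sorting, fell from 1181 ± 246 to 455 ± 50.3 CPM.

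Of 15163 genes tested, 3994 were higher and 4013 lower at day 19, among them 1642 higher and 868 lower by at least 2-fold. With total library size as the only scaling the split was 4652 higher and 3216 lower. The largest rises that met the naming rule were in genes close to silent in culture. The handling of mouse reads is not stated, so mouse reads counted as human could add to femur counts. This was not tested for these genes. SRL reached 71.2 ± 5.53 CPM from 1 count in the 3 culture libraries, a ratio of 5079.9 with a 95% counting interval of 911 to 200690. BAHCC1 and CD9, a tetraspanin of the cell surface, each had 2 counts in culture and reached 40.4 ± 11.6 and 21.6 ± 4.80 CPM. MYBPH, GPSM1, ELAPOR1 and DEPP1 reached 11.6, 20.1, 7.96 and 9.28 CPM. KLF2, a transcription factor of lymphocyte trafficking and quiescence, rose from 0.260 ± 0.169 to 50.3 ± 1.07 CPM (log2 fold change 7.61, SE 0.36; chromosome 19, 16324817 to 16327874). Besides LMO2, large falls that met the naming rule were in SERPINA9, a germinal-centre serpin (-4.81), NLRP4 (-4.56), HTR3A (-4.47), ALOX15 (-4.21), the integrin chain ITGB7 (-4.15) and PCDH7 (-4.05), all as log2 fold changes. ITGB7 overlaps ZNF740 on the opposite strand and NLRP4 overlaps NLRP11, so their counts are uncertain.

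In the germinal-centre B-cell list, 13 of 22 tested genes fell and 5 rose, with the same counts when adjusted over the list alone. S1PR2, a receptor that confines cells to germinal centres, fell from 271 ± 22 to 78.6 ± 6.55 CPM and overlaps DNMT1, while SUGCT rose (log2 fold change 2.99). The list median was -0.54 (camera adjusted p = 0.0103; adjusted p = 0.571 with an estimated correlation). In the homing and adhesion list 9 of 26 genes rose and 10 fell, among them ITGAL, the alpha chain of LFA-1 (log2 fold change -2.42). Its median was 0.04 although camera gave the direction down, and the list was not called (adjusted p = 0.830). In the B-cell receptor and coreceptor list, 9 of 23 genes fell and 4 rose. CD22, an inhibitory coreceptor, fell from 972 ± 113 to 205 ± 4.65 CPM, while PIK3CD, which overlaps CLSTN1 on the other strand, rose (log2 fold change 1.01). The list as a whole was not called (adjusted p = 0.187).

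Genes of MHC class I presentation were higher in the femur in 14 of 15 cases, and none fell, with the same counts when adjusted over the list alone. NLRC5, the transactivator of class I genes, rose from 55.2 ± 5.69 to 250.3 ± 18.2 CPM (log2 fold change 2.18, SE 0.09). PSMB9, an immunoproteasome subunit that overlaps PSMB8 and TAP1, rose by 3.93 and the peptide-trimming enzyme ERAP2 by 2.26 on the log2 scale. In the type I interferon response list 20 of 29 genes rose and 4 fell, with MX2 at 4.62, PARP9, which overlaps DTX3L, at 4.51 and SAMD9L at 3.14 (log2 fold changes). Of 20 immediate early genes 15 rose and none fell, or 16 when adjusted over the list alone, with FOSB, which overlaps ERCC1, at 3.53 and NR4A1 at 2.10. Medians were 0.87, 1.49 and 2.19 for the class I, interferon and immediate early lists. Camera gave adjusted p values of 1.11e-06, 2.00e-04 and 1.29e-04. With an estimated correlation they were adjusted p = 0.571, 0.627 and 0.571.

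Cholesterol synthesis and uptake genes fell almost without exception, 24 of 25 lower and 1 higher. HMGCS1, an early enzyme of the mevalonate pathway, fell from 324 ± 18.2 to 69.5 ± 6.37 CPM (log2 fold change -2.22, SE 0.08), and MVD and ACAT2, which overlaps TCP1, had log2 fold changes of -2.47 and -2.02. The list median was -1.51 (camera adjusted p = 5.43e-14; adjusted p = 0.571 with an estimated correlation). Cytosolic ribosomal protein genes fell in 46 of 47 cases (median -0.46, camera adjusted p = 5.74e-08; adjusted p = 0.627 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 37 of 44 cases and rose in 2 (median -0.45, camera adjusted p = 1.86e-07; adjusted p = 0.571 with an estimated correlation), whereas 9 of 13 mitochondrially encoded genes rose and none fell (camera adjusted p = 0.00527; adjusted p = 0.627 with an estimated correlation). Among G2/M genes 18 of 30 fell and 1 rose (median -0.26, camera adjusted p = 0.00110; adjusted p = 0.571 with an estimated correlation), HMMR having a log2 fold change of -1.25. The proliferation marker MKI67 had 737 ± 173 CPM in culture and 862 ± 50.1 CPM at day 19 (adjusted p = 0.179), and MYC had 414 ± 18.4 and 362 ± 39 CPM (adjusted p = 0.0633).

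Among factors that act on stromal cells, 6 of 15 tested genes rose and 5 fell at day 19, and the list was not called (camera adjusted p = 0.777). HBEGF, a ligand of the EGF receptor, rose from 0.702 ± 0.306 to 12.3 ± 5.09 CPM. BMP7 fell from 691 ± 37.6 to 268 ± 6.51 CPM, TGFB1, which overlaps HNRNPUL1, from 186 ± 14.3 to 117 ± 6.69 CPM and lymphotoxin beta (LTB) from 1.20 ± 0.470 to 0.0448 ± 0.0440 CPM. TNF and LTA were too low to be tested. Of 20 stromal and osteolineage markers 4 could be tested, 1 of which rose and 1 fell. PDGFRB reached 5.17 ± 1.34 CPM from 3 counts in culture. HBB, HBA2, S100A8, S100A9, COL1A2, COL3A1, LUM and POSTN had 0 counts in all 9 libraries, a sum that allows at most 3 counts, while COL1A1 had 39, 16 and 2 counts in the day 40 libraries.

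Camera called 13 of 26 lists at day 19. None of the 13 was called with an estimated correlation, so list statements describe the member counts only. Members of a list varied together across libraries, with estimated correlations of 0.91 for ribosomal protein, 0.54 for immediate early and 0.14 for germinal-centre genes. Called members are therefore not independent evidence. Over all 15163 genes, 3994 were called up and 4013 down at day 19.

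**Figure D1:**
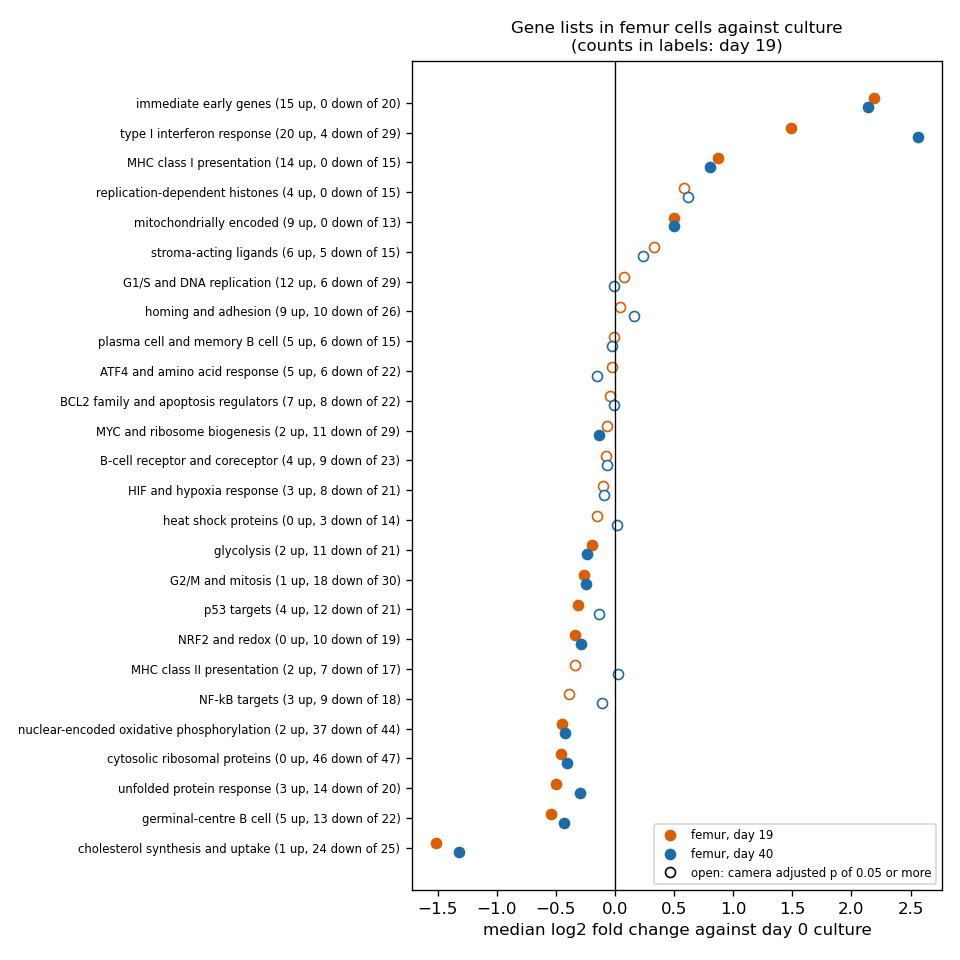
Median log2 fold change of the tested members of 26 gene lists in femur cells against day 0 culture (x axis) for day 19 and day 40, with open points for lists that camera did not call. Immediate early genes had the highest median at day 19, 2.19, and cholesterol synthesis the lowest, -1.51.

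The comparison of day 40 with day 0 asked the same of cells that had been in the mice for longer. By the dates in the titles, day 40 replicates 1 and 2 were not grafted on the date of the culture library of their period. Here 3527 genes were higher and 3538 lower, among them 1416 and 524 by at least 2-fold. BCL6 was at 135 ± 3.89 CPM (log2 fold change -1.67, SE 0.07, adjusted p = 1.27e-08) and CXCR4 at 440.1 ± 47.1 CPM (1.84, SE 0.10). SRL, CD9, BAHCC1, GPSM1, ELAPOR1 and MYBPH were again among the largest rises, together with TNFRSF13B, the receptor TACI of mature B cells, and the sodium channel gene SCN3A. TNFRSF13B and SCN3A had 0 counts in culture and were at least 164-fold and 139-fold higher at day 40, against a floor of 3 counts over the group. TNFRSF13B overlaps the pseudogene TBC1D27P on the same strand. Large falls that met the naming rule were in GASK1B (-6.14), CTTN (-4.74), LMO2 (-4.06), LOXL2 (-3.76), DEPTOR (-3.60), BAIAP2L1 (-3.51) and SEMA4A (-3.50), as log2 fold changes. LOXL2 overlaps ENTPD4 on the same strand and BAIAP2L1 overlaps BRI3 on the opposite strand, so their counts are uncertain. IRF4, a transcription factor of plasma cells, rose from 0.0707 ± 0.122 to 5.39 ± 2.07 CPM.

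The interferon, immediate early, class I, cholesterol, ribosomal protein, oxidative phosphorylation and germinal-centre lists kept the directions seen at day 19. In the interferon list 24 of 29 genes rose and 1 fell, or 26 and 1 when adjusted over the list alone, with PARP9 at 4.86 and MX2 at 4.72 (median 2.56, camera adjusted p = 3.36e-10; adjusted p = 0.374 with an estimated correlation). Immediate early genes rose in 16 of 20 cases (median 2.14, camera adjusted p = 3.10e-06; adjusted p = 0.374 with an estimated correlation) and class I genes in 13 of 15 (median 0.80, camera adjusted p = 1.34e-06; adjusted p = 0.374 with an estimated correlation). Cholesterol genes fell in 24 of 25 cases (median -1.32; adjusted p = 0.374 with an estimated correlation), with HMGCS1 at 89.6 ± 3.03 CPM. Ribosomal protein genes fell in 43 of 47 cases (adjusted p = 0.584 with an estimated correlation), and nuclear oxidative phosphorylation genes and germinal-centre genes fell in 38 of 44 and 13 of 22 cases (both adjusted p = 0.374 with an estimated correlation). Camera called 13 of 26 lists. Among the heat shock genes HSPA1B had 250.3, 13.6 and 30.4 CPM in the 3 day 40 libraries, and its call (log2 fold change 3.50, adjusted p = 0.00449) was lost with limma voom. With total library size as the only scaling the split was 4155 higher and 2650 lower.

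Fold changes against day 0 correlated between day 19 and day 40 across the 15163 genes (Pearson 0.94, Spearman 0.91; genes are not independent replicates). Unchanged groups simulated against the same culture libraries gave 0.51 and 0.46. The covariance was 1.03 against a simulated 0.0315. Both days had 3065 genes higher and 3170 lower in common, where independent lists would share 929 and 936 and the simulation shared 0, and 5 genes went opposite ways. The simulated values already include the sharing of the 3 culture libraries, which gave a covariance of 0.0315 and 0 shared calls. They argue against this sharing as the source of most of the excess. The culture libraries cannot be divided into separate controls of at least 2 each, so this rests on the simulation alone.

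**Figure D2:**
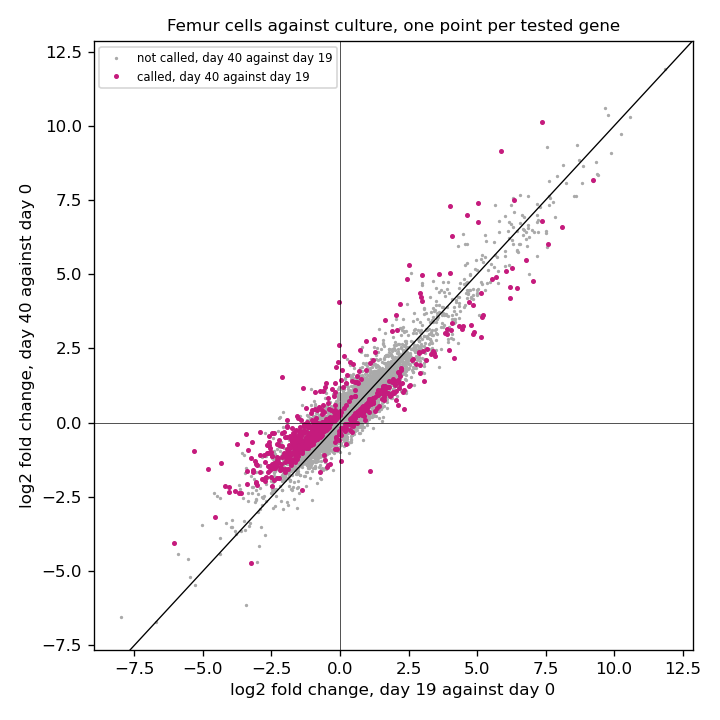
Log2 fold change against day 0 at day 19 (x axis) and day 40 (y axis), with a point for each tested gene and the line of equality. Points for the 710 genes called between day 40 and day 19 are coloured.

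The comparison of day 40 with day 19 tested whether the femur cells differed between the days. At day 40, 8 of 22 germinal-centre genes were higher than at day 19 and 1 was lower, 11 of 29 interferon response genes were higher, and RAG1 and IGLL1 were lower. Neither list was called by camera with an estimated correlation (adjusted p = 0.528). By fry the adjusted p was 0.0322 for the germinal-centre list and 0.0894 for the interferon list. BCL6 rose from 56 ± 2.88 to 135 ± 3.89 CPM (log2 fold change 1.26, SE 0.08, adjusted p = 5.34e-06), SERPINA9 from 2.98 ± 0.776 to 28 ± 12.2 CPM and SUGCT from 37.2 ± 1.58 to 80.1 ± 11.3 CPM. IFI44L, an interferon-induced gene, rose from 1.23 ± 0.353 to 21.2 ± 9.73 CPM (log2 fold change 4.11, SE 0.39, adjusted p = 1.52e-04; chromosome 1, 78619922 to 78646145), and culture had 1.27 ± 0.592 CPM. RAG1, a subunit of the V(D)J recombinase that overlaps RAG2, fell from 15.1 ± 3.33 to 3.12 ± 0.531 CPM (culture 0.427 ± 0.135; chromosome 11, 36510709 to 36593156), and IGLL1, a part of the surrogate light chain, from 322 ± 41.9 to 153 ± 36.1 CPM (culture 4.18 ± 0.656).

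In this comparison 490 genes were higher and 220 lower, 158 and 37 of them by at least 2-fold. Of the 490, 403 had been called lower at day 19 than in culture, 37 higher and 50 neither. Of the 220, 193 had been called higher at day 19 than in culture, 6 lower and 21 neither. Most calls were thus changes back towards culture, although the day 19 libraries enter both comparisons, which by itself favours opposite calls. The counts depended on single libraries. They were 755 and 438 without culture replicate 2, 220 and 65 without day 19 replicate 2, 217 and 63 without day 19 replicate 3, 282 and 99 without day 40 replicate 1 and 289 and 131 without day 40 replicate 2. Further rises by log2 fold change were in SCN3A (2.75), IFI44 (2.65), ASXL3 (2.19), PSD3 (1.93) and SYNPO2 (1.85), and further falls in CTXN1 (-1.31), KREMEN1 (-1.30), TCL6 (-1.22) and CFAP73 (-1.07), which overlaps DDX54. COL27A1 (3.28), LCN8 (-1.55) and MYBPH (-1.05) also met the naming rule, but their calls were lost in at least 1 alternative.

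Of 29 interferon response genes 11 rose, or 21 when adjusted over the list alone, and none fell (median 0.69, camera adjusted p = 6.14e-09; adjusted p = 0.528 with an estimated correlation). The number that rose was 4 when any day 19 library or day 40 replicate 2 was left out, 8 without day 40 replicate 1 and 13 without day 40 replicate 3. IRF7 rose from 15.2 ± 0.488 to 29.9 ± 6.64 CPM. Among germinal-centre genes 8 of 22 rose and 1 fell, or 11 and 4 when adjusted over the list alone (median 0.28, camera adjusted p = 0.00435; adjusted p = 0.528 with an estimated correlation). In the p53 target list 7 of 21 genes rose and none fell, including the death receptor FAS, which overlaps ACTA2 (1.74), the cell-cycle inhibitor CDKN1A (0.94) and SESN1 (0.85) as log2 fold changes (camera adjusted p = 8.55e-05; adjusted p = 0.528 with an estimated correlation). CDKN1A and SESN1 had been lower at day 19 than in culture (-2.01 and -1.86). CD22 and the follicular homing receptor CXCR5, which overlaps BCL9L, rose (log2 fold changes 1.05 and 0.98). Against culture they went from -2.24 and -1.83 at day 19 to -1.19 and -0.84 at day 40. NLRC5, UHRF1, PIK3CD and the BH3-only gene HRK fell (log2 fold changes -0.63, -0.43, -0.36 and -0.86). Against culture these genes were at 2.18, 0.98, 1.01 and 1.62 at day 19 and at 1.56, 0.55, 0.65 and 0.76 at day 40. Camera called 10 of 26 lists, none of them with an estimated correlation.

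**Figure D3:**
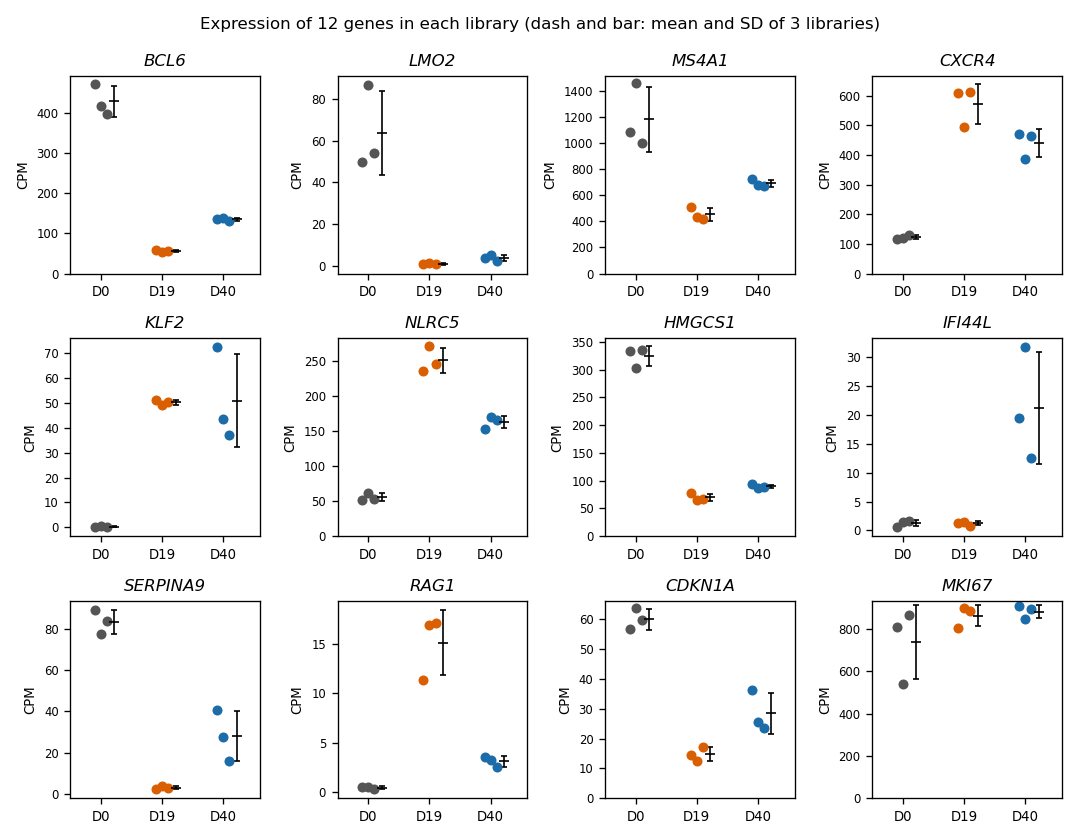
CPM of 12 genes in each library of the 3 groups (x axis: culture D0, femur D19, femur D40), with the mean and SD of 3 libraries as a dash and bar. BCL6 and LMO2 sit lower in every femur library than in any culture library, and IFI44L has 19.5, 31.7 and 12.5 CPM in the day 40 libraries.

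Both femur groups together were compared with day 0 to describe the cells before and after growth in the mice. The mean of the femur groups differed from culture in 8490 genes, 4215 higher and 4275 lower, or 4951 and 3396 with total library size as the only scaling. Camera called 13 lists, with member counts such as 25 of 29 interferon genes up and 24 of 25 cholesterol genes down. With an estimated correlation none of the lists was called (adjusted p = 0.482 for both of these).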

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

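In this part, the tests of RNA from other marrow cells, of the handling of femur cells, and of interferon genes member by member were chosen after the results were seen. The results listed here are differences between the day 19 and day 40 effects against day 0, tested as day 40 against day 19.

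The log2 fold change against day 0 was higher at day 40 in 490 genes and lower in 220. Among lists that camera called at the preset correlation, medians of the difference were 0.69 for the type I interferon response, 0.37 for NF-kB targets, 0.37 for MHC class II presentation, 0.28 for germinal-centre B cell, 0.21 for p53 targets, 0.20 for cholesterol synthesis and uptake, 0.13 for homing and adhesion, 0.094 for the unfolded protein response, -0.068 for G1/S and DNA replication and -0.14 for MHC class I presentation. With an estimated correlation the adjusted p was 0.611 for MHC class I and 0.528 for the rest.

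Of single genes the log2 difference was positive for IFI44L (4.11), COL27A1 (3.28), SERPINA9 (3.24), SCN3A (2.75), IFI44 (2.65), ASXL3 (2.19), PSD3 (1.93), SYNPO2 (1.85), FAS (1.74), TRAC (1.35), BCL6 (1.26), SUGCT (1.11), CD22 (1.05), IRF7 (0.98), CXCR5 (0.98), CDKN1A (0.94) and SESN1 (0.85). It was negative for RAG1 (-2.27), LCN8 (-1.55), CTXN1 (-1.31), KREMEN1 (-1.30), TCL6 (-1.22), IGLL1 (-1.07), CFAP73 (-1.07), MYBPH (-1.05), HRK (-0.86), NLRC5 (-0.63), UHRF1 (-0.43) and PIK3CD (-0.36). In all 29 genes the libraries of the groups did not overlap, which chance gives in 10% of genes for 3 against 3, and the genes were partly chosen for it.

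Other splits of the libraries were tried for each comparison. Fits of the 6 compared libraries alone called 7655 genes for day 19 against day 0, 5984 for day 40 against day 0 and 1100 for day 40 against day 19, and the highest of the other splits called 0 in each, but with 10 splits the real split (1 of 10) cannot reach a share under 0.05. Both femur groups against culture gave 8085 genes and the highest of the other 83 splits 125. Only 1 of 84 splits, the real one, gave as many, a share under 0.05 if libraries can be exchanged across periods. The other splits mix culture and femur, which adds their difference to the spread and lowers the counts. Counts of called lists were less specific. In the same fits camera called 13 lists for day 19 against day 0 (highest other 13, 2 of 10 splits as large), 13 for day 40 against day 0 (highest other 14, 2 of 10) and 11 for day 40 against day 19 (highest other 9, 1 of 10). For both femur groups 11 of 84 splits called at least the real 13 lists, with 15 the highest, so chance is not excluded for the number of lists called. For day 40 against day 19 the 3 other splits that part every period called 0 genes.

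Immediate early genes rose in femur cells in 15 of 20 cases at day 19. After correction for GC content and length 18 were called up, so such a trend does not account for the pattern, while human transcripts of other marrow cells summed to 0.187% of the summed rise of the list, which says nothing of mouse RNA and leaves it open. Handling of the femur cells could also raise these genes, and 0 of 14 heat shock genes were called up at day 19 by edgeR (2 at an unadjusted p under 0.05; 0 by DESeq2 and 1 by limma voom), whereas 4 were called up and 3 down at day 40, where the list was called down without day 40 replicate 1 (median -0.29, adjusted p = 0.0263), so the heat shock genes do not settle whether handling contributed. Since only femur cells were digested and sorted, handling and growth in the marrow cannot be told apart for these genes.

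Ribosomal protein and nuclear oxidative phosphorylation genes were lower at day 19 in 83 of 91 cases. The correction for GC content and length left 70 called and moved the medians from -0.46 to -0.36 and from -0.45 to -0.27, so part of the size may follow such a trend. Other scalings left at least 72 called. The fit without culture replicate 2, which had the highest ribosomal protein share, left 76. It moved the medians to -0.32 for ribosomal protein and -0.36 for oxidative phosphorylation genes, so part of the size rests on that library. None of these accounts for the whole pattern, and a change in the cells with growth in the femur remains a hypothesis that was not tested further. Only femur cells were digested and sorted, so handling cannot be told apart from growth for these genes either.

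At day 40, 11 of 29 interferon response genes were higher than at day 19. The correction for GC content and length left 12 called up (11 before; 4 to 13 when a library was left out), so such a trend does not account for it, while human transcripts of other marrow cells rose by 0.300% of the summed rise of the list, which leaves mouse RNA open. Leaving out day 40 replicate 2 lowered the median from 0.69 to 0.37, just above the bound (0.5 of the value) set for excluding a single library, but by less than the spread between the fits, a condition added after the value was seen, so that test is left undecided. In 58.6% of the 29 members all day 40 libraries lay above all day 19 libraries, so in those members the difference was not confined to 1 library. Chance gives 5% for a gene without any difference, and more where 1 library is high. Members also varied together (estimated correlation 0.48), so this does not decide how far a single library drives the list. Longer growth in the mice may contribute, but the day 40 sorts also fell 11, 26 and 39 days after the culture library of their period, and neither was tested apart.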

How the results depend on the processing

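The correction for GC content and length was chosen after the data were examined, and the other settings were planned. The counts of called genes against day 0 moved by less than 1.5 times in every alternative. They lay between 3390 and 3985 up for day 19 and between 2862 and 3408 up for day 40 when a library was left out. With GC content and length corrected, 4434 genes were up and 3538 down at day 19 and 3952 and 2996 at day 40. With total library size the split moved from 49.9% to 61.1% up at day 40, and the median over all genes at day 19 from 0.013 to 0.10. Of the named genes called against day 0, 105 of 108 at day 19 and 100 of 107 at day 40 were called in every alternative. The calls of AHSA1, HSPD1 and MALAT1 at day 19, and of HSPA1B, MALAT1, MYC, NKG7, PLIN4, PTPRC and TRAC at day 40, were lost in at least 1, while MKI67 and MYC gained a call at day 19 without the count filter (adjusted p = 0.0441 and 0.0235) and MYC without culture replicate 3 (adjusted p = 0.046), and MKI67 gained a call at day 40 without the filter (adjusted p = 0.018) and without culture replicate 3 (adjusted p = 0.0416). No called named value changed its direction.

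For day 40 against day 19, 26 of 54 called named genes were called in every alternative. The counts of 490 up and 220 down became 890 and 434 without a count filter (270 and 70 by at least 2-fold), which tests more genes. DESeq2 called 342 down, limma voom 449 and the fit of the 6 libraries alone 396, and the cause was not tested. Leaving out a library gave 755 and 438 without culture replicate 2, 220 and 65 without day 19 replicate 2, 217 and 63 without day 19 replicate 3, 282 and 99 without day 40 replicate 1 and 289 and 131 without day 40 replicate 2. The counts by at least 2-fold, 158 and 37, became 88 and 15 without day 19 replicate 2, and 87 and 12 without day 19 replicate 3. Up counts by at least 2-fold were 105 without day 40 replicate 1 and 99 without day 40 replicate 2, and reached at most 191 without day 40 replicate 3. Down counts by at least 2-fold reached at most 47 without culture replicate 2. Fewer libraries lower the power to call genes by construction, but some counts rose when a library was left out, and the cause of the rises was not tested. With the replicate block by period 652 genes were up and 314 down, and HSPA4, PECAM1, PLIN4, RUNX2 and SQSTM1 gained a call. The block gave 4176 and 4143 at day 19, 3696 and 3665 at day 40 and 4382 and 4405 for both femur groups, and it changed no other named call.

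With an estimated correlation 0 of the called lists were called in each of the 4 comparisons. The heat shock list, not called between day 40 and day 19 (median 0.15), reversed to -0.16 without day 40 replicate 1 (adjusted p = 0.00173) and was 0.22 without day 40 replicate 2 (adjusted p = 0.0139), and the cause was not tested. The histone list, not called against day 0, was called at day 19 without culture replicate 2 (median 1.15, adjusted p = 0.00652) and with GC content and length corrected (adjusted p = 0.0283), and likewise at day 40 (adjusted p = 0.00631 and 0.0185). The G1/S list was called at day 19 with GC content and length corrected (median 0.13, adjusted p = 0.0473), and the MYC and ribosome list without culture replicate 2 (median -0.16, adjusted p = 0.0237). The homing list lost its call between the femur days without culture replicate 2 (adjusted p = 0.0557), day 19 replicate 2 (0.079) or day 40 replicate 2 (0.0867, median 0.067 from 0.13), and the unfolded protein response list without day 19 replicate 2 (0.095) or day 40 replicate 1 (0.0939). The correlation of the day 19 and day 40 effects lay between 0.92 and 0.94 when a library was left out, and was 0.92 without day 19 replicate 1 or day 40 replicate 3. Genes up at both days numbered 1947 among genes with a mean of at least 5 CPM, which are fewer genes. Depth limits the lowest genes, since 1 count was worth 0.0339 to 0.0475 CPM.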

Other observations

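In this part, the tests of precursor B-cell genes, of FOXO targets and of the segments around single genes were chosen after results were seen. At day 19 the unfolded protein response list fell in 14 of 20 genes and rose in 3, NRF2 and redox genes fell in 10 of 19, p53 targets fell in 12 of 21 and rose in 4, and glycolysis genes fell in 11 of 21 and rose in 2, all called by camera (adjusted p = 8.98e-04, 0.00111, 0.0103 and 0.0227; each adjusted p = 0.571 with an estimated correlation). ALDOA fell from 1053 ± 48.6 to 626 ± 15.7 CPM and CDKN1A from 59.9 ± 3.54 to 14.8 ± 2.32 CPM. Not called at day 19 were HIF and hypoxia response (3 up, 8 down of 21; median -0.10, mean 0.03), ATF4 and amino acid response (5 up, 6 down of 22; median -0.02, mean 0.10), heat shock proteins (0 up, 3 down of 14; median -0.15, mean 0.12) and replication-dependent histones (4 up, 0 down of 15), a list that was called in some alternatives. PFKFB4, a hypoxia-responsive regulator of glycolysis, fell from 17.2 ± 1.37 to 3.87 ± 0.0129 CPM, and HSPA4 fell from 364 ± 9.0 to 208 ± 14.7 CPM.

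Survival and immune groups went both ways at day 19. In the BCL2 family list 7 of 22 genes rose and 8 fell, with the BH3-only genes BMF at -3.08 and HRK at 1.62 and BCL2 at 0.26 (log2 fold changes). NF-kB targets had 3 up and 9 down of 18, MHC class II genes 2 up and 7 down of 17, G1/S genes 12 up and 6 down of 29, and MYC and ribosome biogenesis genes 2 up and 11 down of 29 (camera adjusted p = 0.0989). The plasma cell and memory list had 5 up and 6 down of 15, with a median of -0.01, a mean of 1.27 and the camera direction down. The class II transactivator CIITA rose from 67.1 ± 2.77 to 143 ± 8.59 CPM, while the costimulatory gene CD86 fell from 21 ± 6.03 to 1.71 ± 0.431 CPM. Among markers of other cell types, 2 of 2 tested endothelial markers, 1 of 1 erythroid marker and 3 of 3 T and NK cell markers fell, the neutrophil and monocyte marker LYZ was at 3.91 ± 1.21 and 4.83 ± 0.693 CPM, 1 adipocyte marker rose and 1 fell, and 0 megakaryocyte markers could be tested. TRAC fell from 21.4 ± 3.19 to 6.07 ± 0.992 CPM, B2M rose (0.49), and MALAT1 and PTPRC had log2 fold changes of 0.89 and -0.39.

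Because RAG1 and IGLL1 were higher at day 19, other genes of precursor B cells were tested as a hypothesis, without these 2 genes. Of 19 tested genes 12 were up and 6 down at day 19, and the median of 0.57 lay at percentile 100 of 10000 random lists matched on expression. The random lists hold unrelated genes, so the percentile does not allow for members that move together. Of members chosen after their values were seen, DNTT (6.45), RAG2 (6.19), SOX4 (1.51) and EBF1 (1.20) were up by log2 fold change, CD99 (-1.19) and VPREB3 (-0.60) down. DNTT and RAG2 stayed low, at 1.67 and 2.41 CPM. RAG2 overlaps RAG1, which prompted the test, on the opposite strand, so its counts are uncertain. At day 40 against day 0, 10 were up and 6 down (median 0.24, percentile 99.6), and between day 40 and day 19 the median was -0.24, at percentile 0. A partial precursor B-cell programme, weaker at day 40, may fit these values, but classical members went both ways, and 4 members are also in the germinal-centre list.

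KLF2 and DEPP1, which FOXO factors are known to raise, led to a test of other FOXO targets. Of 21 genes 10 were up and 3 down at day 19, and the median of 0.27 lay at percentile 98.3 of random lists. The percentile again does not allow for members that move together. Between day 40 and day 19, a median of 0.085 with 3 genes up and 2 down already lay at percentile 97.0. RAG2 counted as up in this set and in the precursor set. Of genes chosen after their values were seen, CDKN1B (1.20) and S1PR1 (3.48) were up, but PIK3IP1 (-1.79) and SESN3 (-1.11), also FOXO targets, were down, so FOXO activity may account for a part at most.

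Day 40 profiles lay nearer to day 0 than day 19 profiles. The slope of the day 40 minus day 19 difference on the day 19 minus day 0 difference was -0.17 with all libraries and lay between -0.18 and -0.11 (-0.114 the highest) with different day 19 libraries on the 2 sides, so noise shared through the day 19 libraries does not account for it.

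Gain or loss of chromosome segments was tested for genes switched on or off in the femur, in 3 forms, of which the last 2 were added after the earlier result was seen. In the form set beforehand, the largest median over 524 windows of 100 neighbouring genes was 0.43 at day 19 (chromosome 6, 18128311 to 30343729), above the bound of 0.4 that had been set for a gain. That window holds 27 histone genes, 38 of its genes were up and 8 down, and its quartiles were 0.05 and 1.05, a wide spread for a change in copy number. Around the 16 genes with the largest rises and falls, the median of the 100 nearest genes reached 0.41 in size, against the direction of the gene itself, and in the direction of the gene it reached 0.30 at most, near BAHCC1, between the bounds of 0.25 and 0.4. Windows on chromosome 12 came close at day 19, up to 0.39, and the largest median at day 40 was 0.46 on chromosome 12 (6976186 to 25108334), where the chromosome 6 window had 0.39. The form set beforehand (0.43) therefore leaves open gains on chromosomes 6 and 12, coordinated regulation of neighbouring genes may give such medians too, and the form in the direction of the gene is undecided by its bounds. In that form the median lay under 0.25 for 14 of the 16 genes, which changed by 4.05 to 9.35 in size on the log2 scale. A gain or loss spanning the 100 nearest genes therefore does not account for the change of those 14. For SRL and BAHCC1 it accounts for a part at most. A gain or loss limited to the gene or a few neighbours would hardly move this median, so the test cannot decide on it.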
